A study of Mus musculus with 6 samples.

How the data were processed

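Gene expression was measured in whole mouse pancreas dissected at embryonic day 12.5 (E12.5). There were 3 control and 3 Hox6 null samples, each on 1 array of its own. Hox6 denotes the paralogous transcription factor genes Hoxa6, Hoxb6 and Hoxc6. Per the labels' protocols, RNA was extracted from flash-frozen pancreata, amplified from 10 ng of total RNA with the NuGEN WT-Pico Ovation system and labelled with biotin for Affymetrix arrays. Amplification from so little RNA, and differences in which tissue came along at dissection, can both alter single arrays. The labels call the samples biological replicates and do not say how many embryos went into each, their sex, their litters or the day of hybridization.

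The deposited values are log2 expression values per probe set. The submitters' processing notes name RMA (robust multi-array average: background correction, quantile normalization and probe summary), affy and limma, without versions. Such values are relative to the other arrays of the set and have a floor set by background, so that changes of dim probe sets are understated. No detection calls were used here, and the number of arrays limits the precision. The medians of the 6 arrays lay between 5.97 and 6.02. No values were left out: the table holds 45101 probe sets for the 6 arrays. Array pairs shared between 53 and 166 values equal in all deposited digits, which points to no array deposited more than once.

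Probe sets were named from the platform annotation given with the series. Of all probe sets, 34945 had 1 gene symbol, 932 had several, 9160 had none listed and 64 were array controls. The Entrez identifiers of 34741 of the singly named probe sets were found in the reference gene table (GRCm38.p6), and 0 symbols needed an update. The array files name no genome build, so no coordinates are given. Where a member of a list had no probe set of its own in the annotation used, it was not analysed here.

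The comparison was a linear model with genotype as the single term, fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 on the deposited log2 values, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. It was run over 45037 probe sets without the array controls, and again over 18193 genes, each represented by the probe set with the highest mean over all arrays. A minimum exact permutation p of 0.1 with 3 against 3 samples rules out a per-gene permutation test, so that the adjusted p-values come from limma throughout. Errors of log2 changes are the moderated standard errors. On simulated data with these 18193 genes, 90 of 100 genes changed by 1 log2 unit and 100 of 100 genes changed by 2 were recovered, with 9 false calls. Each simulated gene had the same spread in both groups, and all these changes were present at once, which eases the adjusted threshold. The share recovered from the real arrays can therefore be lower.

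Before the data were examined, 32 gene lists of cell types, signalling pathways and cell states were written down, and 30 of them were tested with camera (limma) at a preset correlation between genes of 0.01, with adjustment over lists. The same lists were tested with camera at an estimated correlation and with fry, which asks whether the members move on balance one way and does not compare the list with other genes. For each list the text gives members past the threshold over all genes and adjusted over the list alone. List medians were set against 10000 random lists matched on mean level in 20 bins. In a simulation in which the endothelial list alone was shifted by -0.5, that list and 0 others were called. Genes were drawn independently of each other in this simulation and in that of single genes. Neither therefore shows how often correlated genes or lists are called in error.

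The genes named in the text follow a rule that was also fixed in advance. It takes the targeted Hox genes, and up to 12 genes per direction past the threshold with non-overlapping arrays. Open places go to genes with an unadjusted p under 0.01, non-overlapping arrays and at least median expression, ranked by size of change. It also takes up to 4 members of each described list by smallest p, the genes recalled from the study's publication and the sex-linked genes. Other genes were chosen after their values were seen, and the text says so.

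Alternatives to filter, normalization, variance prior, array weights, blocking, threshold, probe set choice and set test were run, and each array was left out in turn. After the data had been seen, 4 further fits were added. In 2 of them the mean level of epithelial genes or the Xist level was a covariate. The other 2 left out arrays in which some genes stood far above all other arrays. Lists of 7 possible outside tissues and cell types were also written then, after the genes with the largest mean changes had been seen. The epithelial level was 7.83 to 7.92 in control arrays, 7.92 in null 3, and 8.76 and 8.60 in null 1 and null 2. The fit with this covariate therefore rests mainly on null 3 against the controls and is no independent correction for the share of tissue. Ranges over all alternatives that the text gives for a list cover camera in all fits and fry without a covariate. Fry with a covariate lies outside these ranges. Figures were drawn with matplotlib 3.10.9.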

Results

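The series compared whole pancreas of control and Hox6 null mouse embryos at E12.5, a stage at which the organ consists of branching epithelium with its progenitors and first endocrine cells, surrounded by mesenchyme, vessels, nerves and blood cells. Each group had 3 arrays. Pearson correlations across probe sets were 0.994 to 0.995 among control arrays and 0.980 to 0.987 among null arrays, while pairs of 1 control and 1 null array gave 0.979 to 0.990. The first principal component held 52.2% of the variance, with null replicates 1 and 2 on one side and null replicate 3 on the side of the controls. P-values measure the spread between these samples, which the labels call biological replicates.

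The targeted genes were examined first. Hoxb6 had a log2 level of 9.04 ± 0.29 (SD, n = 3) in control and 8.62 ± 0.34 (SD, n = 3) in null arrays, a difference of -0.42 with overlapping arrays and an adjusted p of 0.393 (limma, all probe sets). The 3 probe sets of Hoxc6 differed by +0.13, +0.47 and +0.73, with adjusted p of 0.551, 0.380 and 0.253. Hoxa6 was not analysed here. The labels do not say which part of each gene was disrupted, and a probe set outside that part checks nothing, so these values neither bear out nor contradict the genotype labels. None of the other 31 Hox genes measured passed the test over all genes. Adjusted over the list alone, 2 of them passed: Hoxd13 was higher by 0.55 ± 0.11 (SE) and Hoxa7 was lower, at -0.60 ± 0.13 (SE). Hoxd13 read 3.67 to 4.50 in all arrays, where a difference carries little weight.

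Of the 13 genes that changed in Hox6 null pancreas 12 were lower, and 5 of these belong to the fixed lists of endothelial, macrophage and erythroid genes. Mpo, the myeloperoxidase of myeloid granules, fell by 2.32 ± 0.16 (SE) on the log2 scale, which is 5.0-fold. The endothelial receptor gene Tek fell by 1.13 ± 0.12, the endothelial lectin gene Clec14a fell by 0.92 ± 0.10 and the lymphangiogenic factor gene Vegfc fell by 1.27 ± 0.13. Ctss, a lysosomal protease of macrophages, changed by -0.93 ± 0.10 and the macrophage surface receptor Adgre1 by -1.35 ± 0.14. Among genes of the erythroid and megakaryocytic lineages, Hemgn changed by -1.68 ± 0.17 and Nfe2 by -0.86 ± 0.09. The cytokine Il33 changed by -2.09 ± 0.21, the secreted metalloprotease Adamts20 by -1.70 ± 0.18, Mdfic by -1.04 ± 0.10 and the vesicle GTPase Rab3b by -1.07 ± 0.11. Rprm, a p53-induced cell cycle regulator, was the single gene that rose, by 1.13 ± 0.12. All 13 had every null array on one side of every control array.

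In total 13 of 18193 genes passed, 1 higher and 12 lower, with adjusted p of 0.0255 for Mpo and 0.0417 for the others (limma, Benjamini-Hochberg). At the level of probe sets 1 of 45037 passed, that of Mpo. The arrays did not overlap for 23.8% of genes, and 3089 genes had an unadjusted p under 0.05 (limma). Chance gives 10% without overlap on average over all splits, but a single split can depart from it where genes are correlated. That share was not computed for the other splits. The gene count rested on single arrays: it was 2 without control 1, 0 without control 2, control 3, null 1 or null 2, and 1536 without null 3, of which 805 were higher and 731 lower. With the Xist level, which differed between the samples, as a covariate it was 0. With the mean epithelial level as a covariate it was 18, of which 14 were higher and 4 lower and 2 were among the 13; both covariates were chosen after seeing the data. The 13 genes kept their sign in these fits, which non-overlapping arrays fix in advance where an array is left out. After quantile normalization had been repeated it was 1, with a minimum fold change of 1.2 also 1, with array weights 155 (37 higher and 118 lower) and with an intensity trend and a robust variance prior together 74.

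**Figure D1:**
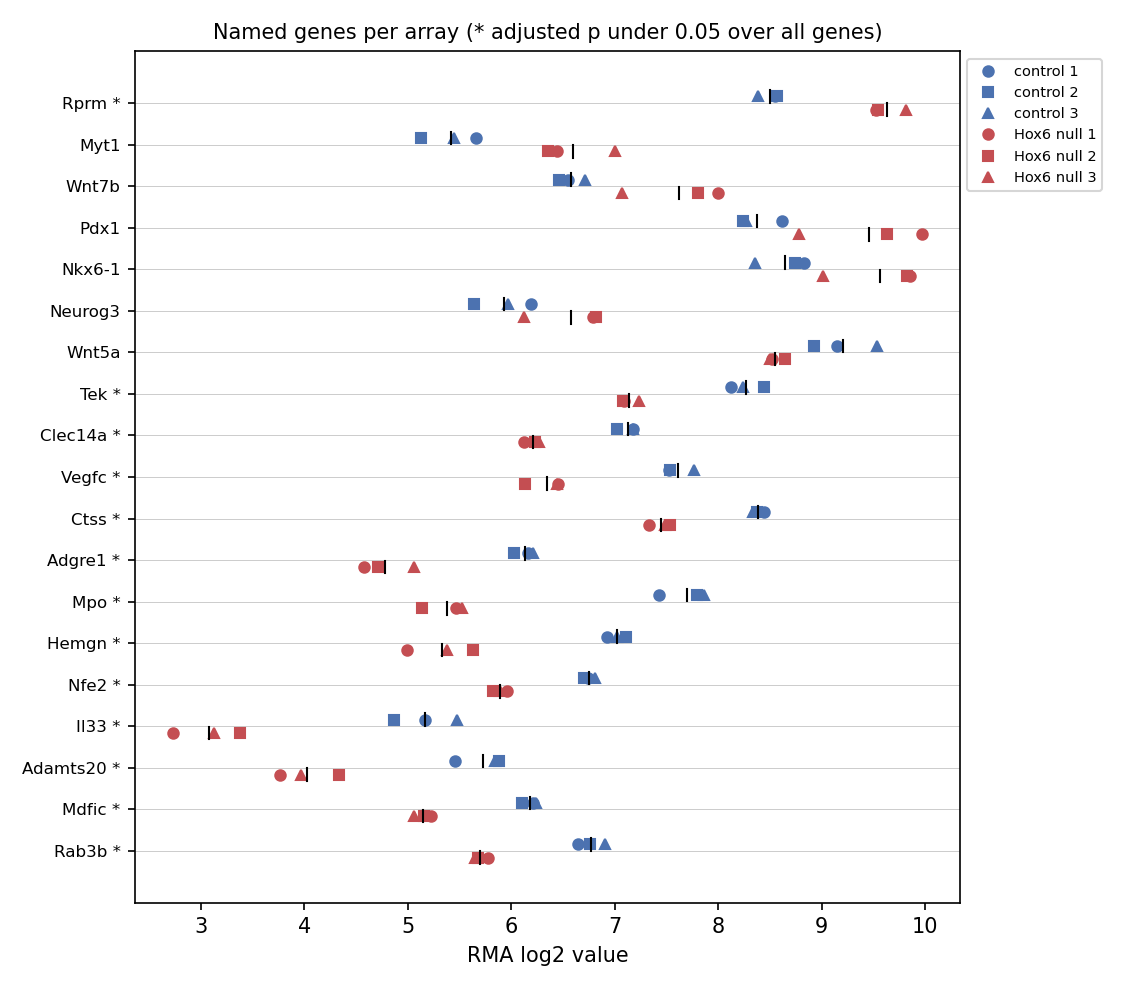
RMA log2 values (x axis) of 19 named genes (y axis) in the 3 control arrays (blue) and the 3 Hox6 null arrays (red); symbols mark replicates and black ticks the group means, and an asterisk marks an adjusted p under 0.05 over all genes. For Mpo the control arrays lie between 7.43 and 7.86 and the null arrays between 5.14 and 5.52, whereas Neurog3 in null 3 (6.12) lies within the controls.

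Of 30 gene lists, 13 shifted by camera at the preset correlation, 6 higher and 7 lower; 5 passed fry, all of them lower, and 0 passed camera with an estimated correlation, where 5 had an unadjusted p under 0.05. Of the 10 ways to split the 6 arrays into 3 and 3, 4 gave at least 13 lists by camera at the preset correlation, the real split among them. The count of lists alone therefore does not set the null arrays apart. Vessel and macrophage genes were lower as groups. All 22 measured endothelial genes had a negative change, with a median of -0.57. Of these, 1 (Tek) passed over all genes and 15 passed adjusted over the list alone, among them Ramp2 (-0.81 ± 0.11, SE) and Emcn (-0.70 ± 0.14). Of 20 macrophage and leukocyte genes 19 were negative, with a median of -0.60. Here 2 passed over all genes and 14 adjusted over the list alone, all of them lower, including the lysozyme gene Lyz2 (-1.13 ± 0.16) and the complement gene C1qb (-0.64 ± 0.09). The list medians of null arrays 1, 2 and 3 relative to the control mean were -0.66, -0.67 and -0.27 for endothelium, and -0.996, -0.685 and -0.405 for macrophages. Both lists passed camera (adjusted p = 1.47e-13 each) and fry (adjusted p = 0.0427 each), but not camera with an estimated correlation (adjusted p = 0.265 with an estimated correlation for each). Epithelial genes were higher in null 1 and null 2, and with the mean epithelial level as a covariate the medians went from -0.57 to -0.22 for endothelium and from -0.60 to -0.32 for macrophages; both lists still passed camera and neither passed fry (0.213 and 0.251).

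Most erythroid genes were lower on average. Of 14 measured, 12 were negative, with a median of -0.43, and 2 passed over all genes. Adjusted over the list alone 4 passed, 1 higher and 3 lower, with Klf1, an erythroid transcription factor, at -0.91 ± 0.18 (SE) among the lower ones. The higher one, the globin gene Hba-a1, read 3.07 to 3.60 in all arrays, where a difference carries little weight. The list passed camera (adjusted p = 8.51e-05), though not with an estimated correlation (adjusted p = 0.584 with an estimated correlation), and did not pass fry (0.157). With the stricter filter on dim probe sets it did not pass camera either (adjusted p = 0.111, range over all alternatives 3.63e-09 to 0.584), nor with the epithelial covariate (0.286), where its median went from -0.43 to -0.04 (-0.0444). Its medians in the null arrays were -0.24, -0.85 and +0.01.

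Matrix, mesenchyme and mesothelium genes were lower as well. Of 43 extracellular matrix genes 37 were negative, with a median of -0.39; none passed over all genes, and adjusted over the list alone 22 passed, 21 of them lower. The proteoglycan genes Dcn and Lum stood at -0.88 ± 0.10 (SE) and -2.12 ± 0.31, and Col12a1 and Fbln5 at -0.94 and -1.43, with the same sign in 3 of 4 and in 1 of 2 probe sets. In the pancreatic mesenchyme list, which shares 10 genes with the matrix list, 32 of 38 genes were negative and the median was -0.25. Over all genes 0 passed, and adjusted over the list alone 5 passed, all lower, among them the transcription factor Twist1 (-1.30 ± 0.18). Of 15 mesothelium genes 13 were negative, with a median of -0.56, and adjusted over the list alone 9 passed, all lower, led by Muc16 (-1.06), Upk1b (-1.39), Upk3b (-0.63) and Rspo1 (-1.68). The 3 lists passed camera (adjusted p of 3.83e-12, 3.27e-08 and 2.36e-07) and fry (0.00826, 0.0427 and 0.0427). With an estimated correlation they did not (adjusted p = 0.0839 with an estimated correlation for matrix and 0.265 for each of the other lists). With the epithelial covariate the medians became -0.24 for matrix, -0.11 for mesenchyme and -0.16 for mesothelium, none passed fry, and mesenchyme no longer passed camera (adjusted p = 0.165, range over all alternatives 2.64e-09 to 0.265).

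Spleen primordium genes passed camera but not fry, and smooth muscle genes passed neither. Spleen primordium genes, of which 7 of 9 were negative, had a median of -0.35 and passed camera (adjusted p = 0.0217), with 0 genes past the threshold over all genes or adjusted over the list alone; adjusted p = 0.584 with an estimated correlation and 0.447 with fry. The call was lost without control 3, null 1 or null 2 (camera, adjusted p of 0.0552, 0.206 and 0.0885), with medians of -0.12, -0.44 and -0.19. It was also lost with the stricter filter on dim probe sets (0.0976) and with the epithelial covariate (0.570), where the median turned to +0.07 (0.0735); the range over all alternatives was 9.61e-05 to 0.584. Null 3 lay among the controls for Tcf21 (11.24) and Nkx2-5 (7.57). Tlx1, required for spleen formation, stood at -0.82 with overlapping arrays. Smooth muscle genes had a median of -0.18 and did not pass (adjusted p = 0.0672), with Acta2 at -1.02 ± 0.20 (SE) and Actg2 at -0.85 as the 2 members past the threshold adjusted over the list alone and 0 over all genes. The list passed camera without control 3 (adjusted p = 0.00696), with the stricter filter (0.0400), with the replicate block (0.0199) and with the mean over all probe sets of a gene (0.0434), in a range over all alternatives of 0.00696 to 0.527.

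**Figure D2:**
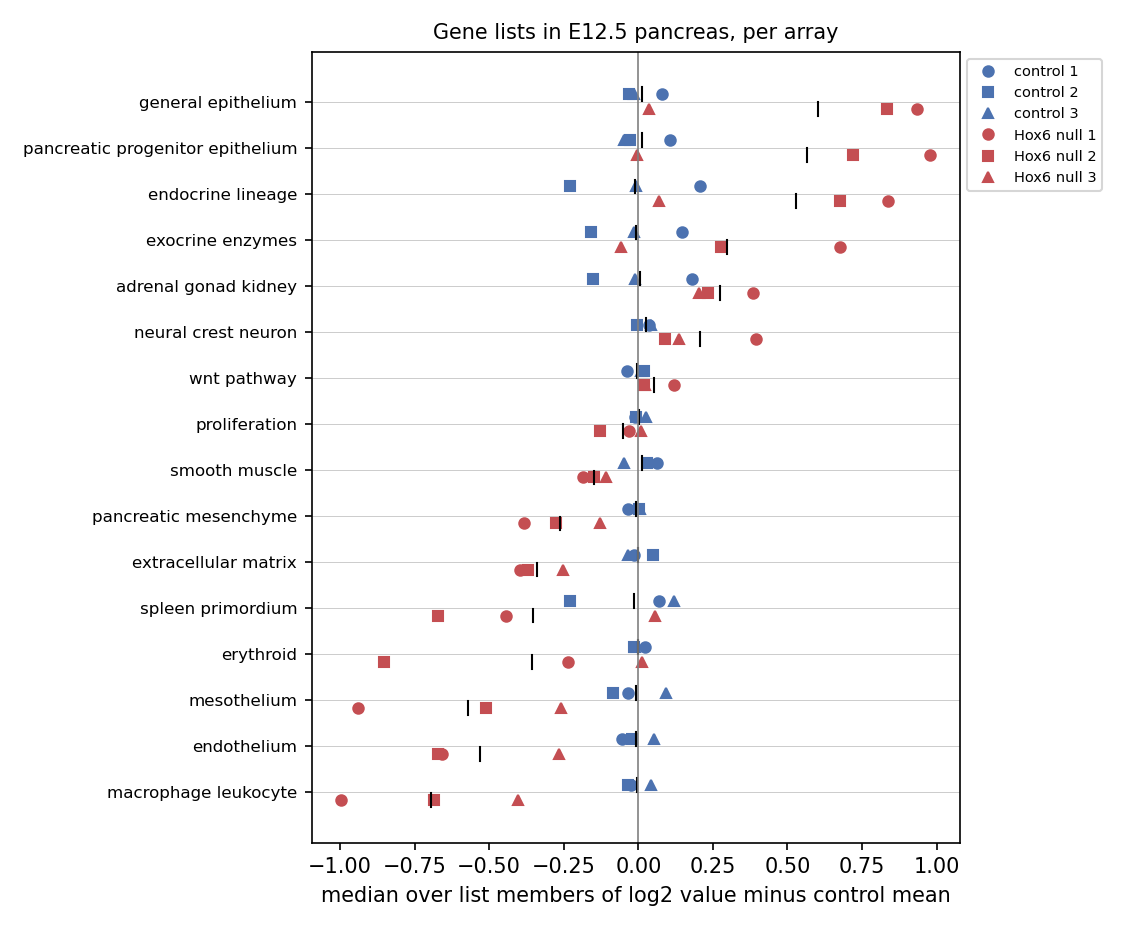
Median over the members of each of 16 gene lists (y axis) of the log2 value minus the control mean (x axis), for the 3 control arrays (blue) and the 3 Hox6 null arrays (red); symbols mark replicates and black ticks the group means. Macrophage and endothelium medians are negative in all 3 null arrays, while the general epithelium median is 0.94 and 0.83 in null 1 and null 2 and 0.04 in null 3.

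Epithelial gene groups were higher in null arrays 1 and 2, and null 3 lay among or close to the controls. Of 24 general epithelial genes, such as the claudins Cldn3 and Cldn4, 21 were positive with a median of +0.55; the medians of the null arrays were 0.94, 0.83 and 0.04. Of 24 pancreatic progenitor genes 23 were positive (median +0.56; null arrays 0.98, 0.72 and -0.004). Of 43 genes of the endocrine lineage 40 were positive (median +0.54, null arrays 0.84, 0.68 and 0.07). Of 25 exocrine enzyme genes 23 were positive (median +0.37, null arrays 0.68, 0.28 and -0.06), and their median was +0.22 without null 1. Over all genes 0 members of these lists passed. Adjusted over the list alone 1 passed, the zinc finger gene Myt1 of the endocrine lineage, at +1.19 ± 0.21 (SE) with null levels of 6.44, 6.35 and 7.0 against 5.13 to 5.66 in controls. The 4 lists passed camera (adjusted p of 7.06e-06, 3.66e-05, 1.18e-07 and 0.00746) but not fry (0.306, 0.306, 0.306 and 0.447). With an estimated correlation none did: adjusted p = 0.584 with an estimated correlation for the first 3 and 0.644 for exocrine enzymes. Without null 1 the exocrine list no longer passed camera (adjusted p = 0.206, range over all alternatives 1.64e-05 to 0.644). With the mean epithelial level as a covariate the endocrine and progenitor medians became +0.03 and -0.03.

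Genes recalled from the study's publication, partly chosen on these samples and so no independent evidence of direction, comprised Wnt5a, Wnt antagonists and endocrine regulators. Wnt5a, a secreted Wnt ligand, stood at 9.20 ± 0.31 (SD, n = 3) in control and 8.55 ± 0.08 (SD, n = 3) in null arrays, a difference of -0.65 ± 0.16 (SE) that did not pass over all genes (adjusted p = 0.170); its other 3 probe sets gave -0.43, -0.18 and -0.31. The Wnt antagonist Frzb stood at -2.53 ± 0.55, with null levels of 3.79, 3.84 and 5.94, and Dkk1 at -0.61 with its level in control 2 (5.10) above all other arrays. Pdx1 (+1.08 ± 0.29), Nkx6-1 (+0.92), Nkx2-2 (+0.77), Sox9 (+0.70), Insm1 (+0.69) and Neurog3 (+0.64 ± 0.22), transcription factors of pancreatic progenitors and the endocrine lineage, were higher on average. Ptf1a and Pax6 differed by +0.61 each, Pax4 by +0.27 and Gcg, the glucagon gene, by +0.22. Of the 13 measured, 0 passed over all genes and 8 passed adjusted over the list alone, 6 higher and 2 lower (Frzb and Wnt5a). The list passed camera (adjusted p = 0.0469), not with an estimated correlation (adjusted p = 0.584 with an estimated correlation) and not fry (0.320). Its call was lost without control 2, control 3, null 1 or null 2 (adjusted p of 0.0628, 0.0971, 0.112 and 0.148, range over all alternatives 0.00105 to 0.928). With the mean epithelial level as a covariate the median of the list went from +0.61 to -0.055 (adjusted p = 0.928). The 8 genes became 2 without control 2, 3 without control 3 and 0 without null 1 or null 2.

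The wider list of Wnt ligands, receptors and modulators, which holds 3 of those genes and is therefore not fully independent of the study either, did not shift as a whole. Of 61 members 36 were positive and 25 negative; the median was +0.08 whereas camera gave the direction as down (adjusted p = 0.905). Over all genes 0 passed, and adjusted over the list alone 8 passed: Wnt7b was higher (+1.05 ± 0.23, SE) and 7 were lower, among them Prickle2 (-0.59), Rspo3 (-1.75), Fzd1 (-0.62) and Frzb. Leaving out any of the 3 controls, null 1 or null 2 made this count 0, and leaving out null 3 made it 21. Targets of beta-catenin signalling gave a median of +0.05 (adjusted p = 0.719), with 0 of 18 past the threshold over all genes or adjusted over the list alone.

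Other signalling pathways did not pass as lists. Hedgehog genes had a median of -0.12 (adjusted p = 0.152, and 0.0407 without null 3, in a range over all alternatives of 0.0407 to 0.880), with 2 past the threshold adjusted over the list alone, the antagonist Hhip at +0.84 ± 0.10 (SE) and the co-receptor Boc at -0.57 (the same sign in 2 of 3 probe sets). Notch genes had a median of +0.17 (adjusted p = 0.433), with 4 past it adjusted over the list alone, of which Dll1 (+0.49) and Dll3 (+0.67), ligand genes, were higher and Hey2 (-0.94) and Heyl (-0.57), vascular target genes, lower. The BMP, TGF-beta and activin list (median -0.02, adjusted p = 0.212) had 3, with Tgfbr2 at -0.70, Tgfb1 at -0.998 and Id4 at +0.66; the other probe sets of Tgfb1 (+0.09, 0.087) and Id4 (-0.40 and -0.03, -0.0328) had the opposite sign. Retinoic acid genes (median +0.06, adjusted p = 0.439) had 2, Cyp26b1 at -1.07 and Rarb at -0.82, and FGF and EGF genes (median -0.05, adjusted p = 0.941) had 0. Over all genes 0 members of these lists passed.

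Lists of cell state and of neighbouring tissues completed the comparison. Proliferation genes (median -0.06, adjusted p = 0.239), p53 and apoptosis genes (+0.05, 0.701), immediate early and heat shock genes (-0.04, 0.348), hypoxia and glycolysis genes (+0.0009, 0.719) and ribosomal protein genes (+0.01, 0.697) did not pass. Adjusted over the list alone, 1 hypoxia gene (Ndrg1, +0.50) and 1 ribosomal protein gene (Rps6, -0.78, with its other probe set at +0.36) did. Genes of neural crest and neurons had a median of +0.26 (adjusted p = 0.0567) with 0 past the threshold either way, and passed without control 1, null 1 or null 2 (adjusted p of 0.0405, 0.0304 and 0.0365). They also passed with repeated quantile normalization (0.0279), median centring (0.0427), the replicate block (0.0210), the mean over all probe sets of a gene (0.00470) and the epithelial covariate (0.00651), in a range over all alternatives of 0.00470 to 0.348. The adrenal, gonad and kidney list had a median of +0.26 and passed camera (adjusted p = 0.00451), with Pax8 at +1.05 (0.68 without null 1) and 0 genes past the threshold either way; adjusted p = 0.584 with an estimated correlation and 0.157 with fry. It did not pass with the epithelial covariate (0.0758) or with null 2 as the only null array (0.159), in a range over all alternatives of 0.000474 to 0.584. Stomach and intestine genes (median +0.14, adjusted p = 0.276), hepatocyte genes (-0.10, 0.711) and the other Hox genes (+0.11, 0.368) did not pass. Stomach and intestine genes did with the Xist covariate (0.0102, range over all alternatives 0.0102 to 0.813), and their median turned to -0.15 with the epithelial covariate. Hepatocyte genes did without control 3 (0.0224, range over all alternatives 0.0224 to 0.971), and their median was +0.24 without control 2. The other Hox genes passed without null 1 (0.0360) and, with a median of +0.40, with the epithelial covariate (7.77e-08, range over all alternatives 7.77e-08 to 0.974), and their median was -0.06 (-0.061) without null 3. Of the remaining higher genes taken in by the naming rule, Nepn (+1.36), Arg1 (+0.999), Hprt (+0.92), Rhov (+0.95), Myo5b (+1.14), Gsta3 (+1.14) and Nupr1 (+0.99) had non-overlapping arrays and did not pass.

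Some genes stood apart in single arrays, and the Xist level differed between samples. Null 1 had 53 genes over 1 log2 unit above all other arrays. Among them were Cuzd1, a member of the exocrine list, Car4 and Prap1 (12.22 in null 1, 8.55 in null 2 and at most 4.94 elsewhere). Null 3 had 37, among them the neural transcription factor genes Zic1, Nhlh2 and Sox2. Control 2 had 20, among them the liver genes Alb and Apoa2. These genes were chosen after their values were seen. Xist, expressed from the inactive X chromosome of females, stood at 11.18, 10.68 and 4.13 in the controls and at 6.87, 3.87 and 4.07 in the null arrays. The Y-linked genes Kdm5d, Uty and Eif2s3y differed by +0.56, +0.51 and +0.38 on average. In controls 1, 2 and 3 Kdm5d stood at 8.85, 9.14 and 8.78 and Eif2s3y at 7.84, 8.045 and 7.74. Uty stood at 5.33, 5.77 and 5.64 there, lower than in control 3 in control 1 alone. High Xist in controls 1 and 2 thus did not go with low levels of Y-linked genes. Xist alone therefore does not sort these samples by sex, and whether they held tissue of both sexes was not tested. None of the 5 sex-linked genes measured passed over all genes or adjusted over the list alone; Tsix differed by +0.11.

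**Figure D3:**
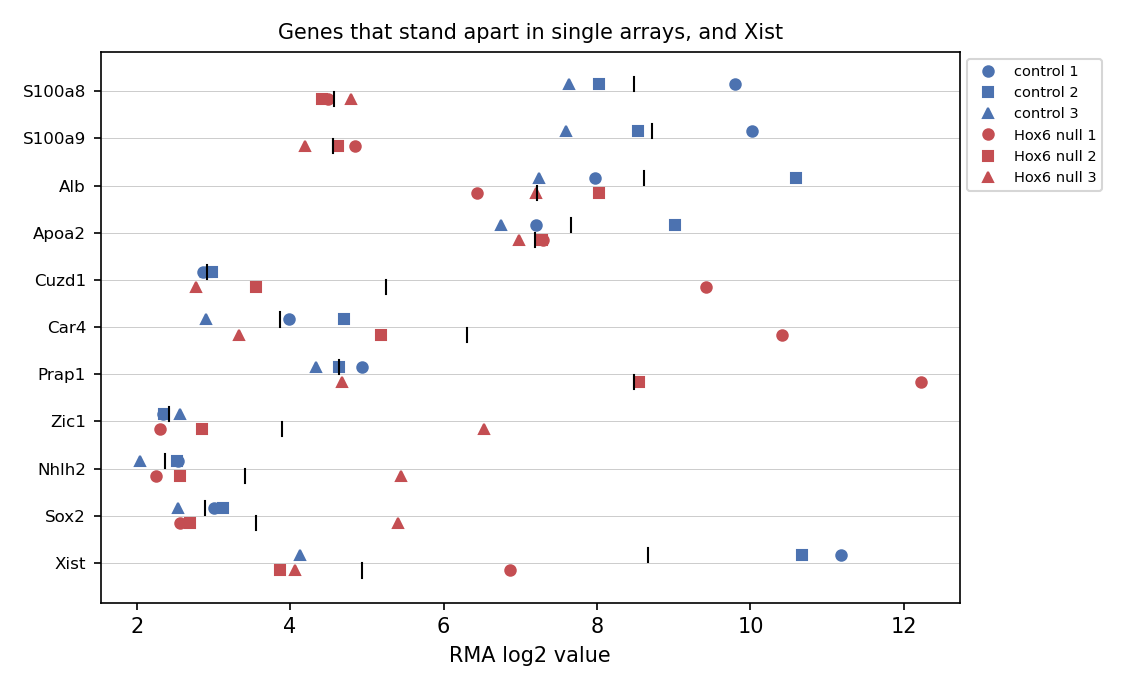
RMA log2 values (x axis) of 10 genes that stand apart in single arrays and of Xist (y axis) in the 3 control arrays (blue) and the 3 Hox6 null arrays (red); symbols mark replicates and black ticks the group means. Cuzd1 reaches 9.42 in null 1 and at most 3.56 elsewhere, Zic1 reaches 6.53 in null 3, and S100a8 lies between 7.64 and 9.80 in controls and between 4.42 and 4.79 in null arrays.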

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

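Array control probe sets, which were left out of the report's comparisons, were tested separately, and 0 of 64 passed the threshold. All 3 probe sets of 18S ribosomal RNA were higher in every null array than in every control array, by 0.29 on the log2 scale on average (12.93 against 12.63), with adjusted p-values between 0.0519 and 0.0540 (limma, over the 64 control probe sets). Of the hybridization controls, added to each sample in fixed amount, the 6 probe sets of bioB were higher by 0.40 on average (10.49 against 10.09), with adjusted p-values between 0.0540 and 0.220, and 4 of them had every null array above every control array. The 4 of bioC were higher by 0.30, with 2 such probe sets, while the 4 of bioD and the 4 of cre differed by 0.06 (0.055) and 0.003 on average, with 0 such probe sets. Of the 64 control probe sets 23 had every null array above every control array, and 24 had an unadjusted p under 0.05. No explanation was tested for these values.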

How the results depend on the processing

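The fits with the epithelial or Xist level as a covariate and those without 2 arrays were chosen after seeing the data; the cause of a shift was not tested unless stated. The fit without null 1 and null 3 sets null 2 alone against 3 controls and assumes that it varies like them, so its counts describe 1 array. Genes past the threshold, 13, became 20 with the milder filter on dim probe sets, 1 after repeated quantile normalization, 8 with median centring, 74 with an intensity trend and robust prior, 155 with array weights, 1 with a minimum fold change of 1.2, 88 at adjusted p 0.10 and 426 at unadjusted p 0.01 with a 1.5-fold change. They became 18 with the epithelial covariate (14 higher and 4 lower), 0 without control 2 and null 1, 0 with the Xist covariate and 928 without null 1 and null 3. Leaving out 1 array gave 0 to 1536. Wherever the 13 genes were measured they kept their sign. As their arrays did not overlap between groups, leaving out or weighting arrays could not turn it. The stricter filter on dim probe sets left 4 of the 13 to be tested, and these 4 passed. The others of the 13 were removed before the test, as their mean level lay below that of the median gene (6.81). All 13 were among the 155 and the 1536. Probe sets past the threshold, 1, became 16 with the stricter filter on dim probe sets, 0 after repeated quantile normalization, 63 with trend and robust prior, 41 with array weights, 0 with a minimum fold change, 26 at adjusted p 0.10, 923 at unadjusted p 0.01 with a 1.5-fold change, 0 without variance moderation, 10 with the epithelial covariate, 0 without control 2 and null 1, 0 with the Xist covariate and 936 without null 1 and null 3, with 0 to 1902 when 1 array was left out.

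Deviations of same-numbered control and null arrays correlated at 0.159, -0.038 and 0.1, and those of differently numbered ones at -0.17 to 0.055. With 3 arrays per group these values neither show nor exclude a pairing of the samples by number. With the replicate block, a fit with fewer residual degrees of freedom, genes past the threshold numbered 0, probe sets 1, lists 15 and genes of the Wnt list 11.

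Lists past the threshold, 13, became 0 with correlation estimated per list (5 had an unadjusted p under 0.05), 5 with fry and 6 with the epithelial covariate, 2 higher and 4 lower. In that last fit the progenitor, exocrine and spleen medians turned to -0.0349, -0.12 and +0.0735 and that of the recalled study genes to -0.055, while the other Hox genes (median +0.40) and neural crest and neuron genes (+0.09, 0.0909) passed. With the Xist covariate 14 lists passed, 7 higher and 7 lower. Genes of the Wnt list past the threshold, 8, ranged from 0 to 21 with 1 array left out, and the recalled study genes, 8, from 0 to 11, or 5 with the stricter filter.

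Genes that changed sign did not pass in the first place. With the epithelial covariate Pnliprp1 became -0.0748, Cel -0.0835, Ambp -0.0454, Serpina1b -0.27, Dhrs3 +0.0088, Tcf21 +0.0735, Nkx2-5 +0.15, Ptf1a -0.17, Pax6 -0.0645, Gcg -0.055, Pax4 -0.38 and Tsix -0.0924. Without control 2 and null 1, Dkk1 became +0.0703, Pax4 -0.10 and Tsix -0.12. With 1 array left out Pax4 ranged from -0.0307 to 0.53 and Tsix from -0.0066 to 0.21, and Tyms was -0.0682 as the mean of its probe sets. The odds ratio near the Hox clusters became 0.94 with 500 genes. Of all other values of named genes and lists, 249 moved past the threshold and 184 fell short of it, without a change of sign for genes or of camera's direction for lists. Lists that did not pass and had medians near 0 changed the sign of the median under some alternatives. Signal over background limits dim genes, for which no detection calls were used.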

Other observations

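The tests of the splits for probe sets and gene lists and all tests of tissue mixture and sex in this part were chosen only after the results were seen; the test near the Hox clusters and the splits for genes were planned. The criteria for the share of tissue, for uterine and intestinal epithelium and for the null genotype in null 1 were also revised after a first version of each had been run and its outcome seen. In the first version the count of lists past fry with the covariate, 0 of 5, left the share of tissue undecided, at least 3 members with their Fisher p counted as fitting uterine epithelium, and a low count of shared genes or of members counted against the null genotype and intestinal epithelium.

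Some genes of neutrophils outside the fixed lists, named after their values were seen, were lower in the null arrays beside Mpo, while others were not. S100a8 differed by -3.92 ± 0.51 (SE) and S100a9 by -4.16 ± 0.55, the former at 7.64 to 9.80 in controls and 4.42 to 4.79 in null arrays, and neither passed over all genes (adjusted p = 0.0698 each, limma). The stefin genes Stfa3 (-3.27) and Stfa2l1 (-3.38) had non-overlapping arrays too, with adjusted p of 0.154 and 0.164. Camp (-1.67) and Ngp (-1.41) overlapped between groups. Within the controls the levels of S100a8, S100a9, Stfa3, Stfa2l1, Camp and Ngp were highest in control 1, whereas that of Mpo was highest in control 3. In a list of 18 further neutrophil genes the median was -0.07 (-0.067), with 11 lower and 7 higher; 0 passed over all genes and 3 had an unadjusted p under 0.05, of which 1 was lower (limma). In it the granule genes Elane, Prtn3 and Mmp9 differed by -0.29, -0.19 and -0.07 (-0.0741) with overlapping arrays, and 1 gene exceeded all other arrays by over 1 log2 unit, Lcn2 in null 1. Some of these genes were dim in all arrays, such as Elane (3.01 to 3.89), Ctsg (2.73 to 2.985) and Cxcr2 (3.18 to 3.66), where a fall could hardly be seen. Prtn3 (5.66 to 6.17) and Mmp9 (5.43 to 5.68) read higher. The median of this list therefore does not decide whether neutrophil genes fell as a group.

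Myt1 was the endocrine gene with the smallest p, and its level in null 3 (7.0) was above those in null 1 and null 2. Null 3 had an epithelial level (7.92) close to that of control 1 (7.92), but also neural genes far above all other arrays. The fit with the epithelial level as a covariate rests mainly on null 3 and so is no separate evidence for single genes. Whether the high level of Myt1 in null 3 goes with the neural genes was not tested. With the epithelial level as a covariate its difference was +1.56 (adjusted p = 0.110, range over all alternatives in which it was measured 0.0227 to 0.484). Rprm differed by +1.32 in the same fit (adjusted p = 0.0463, range over all alternatives 0.00868 to 0.477).

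The first pattern weighed is the lower level of endothelium, macrophage, mesothelium, matrix and mesenchyme lists. A larger share of epithelium as the only cause would dilute all other cell types alike, yet the mesenchyme median minus the endothelium median was 0.14 to 0.40 in null arrays and at most 0.02 in control arrays, a shift of 0.27 between groups. A distortion that depends on signal level is argued against by the random lists matched on level, among which all 5 medians lay at percentile 0. A partial contribution of tissue share stays open. With the epithelial level as a covariate the endothelium median moved from -0.57 to -0.22 and the macrophage median from -0.60 to -0.32. A single member's standard error was 0.16 and 0.18 there, no error of the medians was computed, and 0 of the 5 lists then passed fry. That fit rests mainly on null 3, where these medians were -0.27 and -0.405, so it cannot decide how large that contribution is. By camera 4 of the 5 stayed lower past the threshold in that fit (adjusted p of 6.00e-05 for endothelium, 9.79e-06 for macrophages, 0.0171 for mesothelium and 1.15e-07 for matrix, but 0.165 for mesenchyme). Over all alternatives apart from fry with a covariate, the adjusted p ranged up to 0.265, or 0.0839 for matrix, both by camera with an estimated correlation. With the epithelial covariate, fry gave an adjusted p of 0.422 for mesothelium and 0.117 for matrix. A different mix of sexes was examined only through the Xist level as a covariate. In that fit each list kept at least 0.938 of its median and all 5 passed camera. This argues against an effect that follows the Xist level as the only cause. As Xist alone does not sort these samples by sex, the fit cannot exclude a different mix of sexes. The endothelium median was -0.69 there with a member's standard error of 0.18 (0.183), and 0 of the 5 passed fry (adjusted p = 0.114 each) in that fit with fewer residual degrees of freedom. An effect of the genotype on these cell types stays open. Of the 64 array control probe sets, 23 also had every null array above every control array, and a link with these lists was not tested.

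The second pattern is the higher level of epithelial, progenitor and endocrine lists in null 1 and null 2. A larger share of epithelium in these samples is a candidate explanation, as the 3 lists moved by nearly the same amount in each null array. With the epithelial level as a covariate the endocrine median was 0.03 (0.0323) and the progenitor median -0.03. That fit rests mainly on null 3, where the medians were 0.07 and -0.004, so it adds little to the values per array. Such a share could come from dissection or from the genotype, and the data cannot separate these, since null 3 did not show it. A smaller change of endocrine genes beyond that of epithelium as a whole stays open. The standard error of a typical single member was 0.20 in that fit, and no error of the list median was computed.

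The third pattern is the 53 genes over 1 log2 unit above all other arrays in null 1. Whether the null genotype contributed stays open: 11 of the 53 were above every control in both other null arrays (31 in null 2 and 17 in null 3), against 16.6% of all genes (38.2% and 30.6%), but genes chosen for standing above the other null arrays cannot decide this. Intestinal epithelium stays open too: the largest excess of a member of its list was 0.60 (0.597), but that list, written after the data were seen, leaves out Guca2b, Car4, Prap1 and Aoc1, genes known from intestine, with excesses of 4.84, 5.22, 3.67 and 3.19. Maternal uterine epithelium is a possible source that these values leave open: 4 of 25 measured members of its list (Lcn2, Lrg1, Gabrp and Pax8) exceeded all other arrays by over 1, Fisher's exact p = 7.76e-07 (one-sided), but Ltf (5.37 against 5.35 in control 1) and Muc1 (7.80 against 7.47 in null 2) did not, and Lcn2 is also in the neutrophil list. That list was written after the genes with the largest mean changes had been seen, so its count is not independent.

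The other lists of outside tissues gave these counts of members over 1 log2 unit above all other arrays. For neural tube and somite it was 6 of 25 in null 3 (Zic1, Sox2, Msx3, Neurod4, Nhlh2 and Uncx) and 0 in every other array. For yolk sac endoderm it was 3 of 18 in control 2 (Apom, Apob and Apoc2), of which Apob and Apoc2 are also in the hepatocyte list. For decidua (15 measured), kidney proximal tubule (14) and intestinal epithelium (14) it was 0 in all arrays.

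Sequence of the donor strain carried along with the targeted alleles would place changed genes near the Hox clusters on chromosomes 6, 11 and 15. Of the 200 genes with the smallest p, 16 (8%) lay within 20 Mb of these clusters, against 6.54% of the 18031 genes placed on GRCm38.p6, an odds ratio of 1.25 (1.245; 95% interval 0.695 to 2.09; Fisher's exact p = 0.387, two-sided). The interval includes 1 and reaches past 1.5, so enrichment is neither shown nor excluded for these 200 genes, for which the test was set. With the 500 smallest p the odds ratio was 0.94 (0.9445; 95% interval 0.631 to 1.37), which stays under 1.5 for that wider set.

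The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Genes past the threshold numbered 13 in the real split and at most 0 in any other, where genes with an unadjusted p under 0.01 numbered 908 and at most 330; 1 split, the real one, reached 13 genes. Probe sets past the threshold numbered 1 in the real split and at most 0 in the others, so that 1 split reached that count. For gene lists under camera with the preset correlation, 4 of the 10 splits gave as many as the real 13 and the highest other gave 18, the split of control 1, null 1 and null 2 against the rest.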
